A study of Gallus gallus with 12 samples.

How the data were processed

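Per the labels, poly(A) RNA of each library was made into a strand-specific TruSeq library and sequenced as paired-end reads. The deposited values are counts per gene and library, whole numbers that the authors did not normalise, in 1 file per library. The submitters' processing notes name TopHat2, SAMtools, featureCounts and DESeq2 and the chicken genome build galGal4. Their versions and roles, the gene annotation, the counting strand, the handling of reads that fit several genes and any filter are not given in the sources used here. Genes that share sequence with a paralog are therefore uncertain. Of 21350 listed features, 13763 carry a symbol that a current RefSeq gene table holds and 308 a synonym in it, and 3672, 1410 and 631 carry names starting with ncRNA, uPROT and pPROT. That table was used for names only, and no reference genome was used here, so checks of GC content and gene length are not analysed here. The 12 libraries fell into 6 groups of 2 by their titles, and all were used. Replicates of a group differed by more than counting noise in each of the 6 groups, with a chi-square per degree of freedom from 13.27 to 89.45. Totals ran from 51233721 to 106079374 counts, so counting error is small beside the spread between replicates (common biological coefficient of variation 0.128).

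Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Features were kept by filterByExpr with its minimum count of 10, which left 18979, and scaled by TMM factors, which ran from 0.9521 to 1.041. 1 quasi-likelihood model with a term per group was fitted to all 12 libraries, which leaves 6 residual degrees of freedom (median prior degrees of freedom 4.6). Each factor was compared with Control by edgeR's quasi-likelihood F test, two-sided, and OSR1 with OSR2 and KLF2 with KLF4 in the same fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, and every adjusted p of a gene in the text is from this test unless another is named. The p-values measure only the spread between these libraries, since the labels do not say how far the 2 replicates of a group are separate in origin. CPM values use the scaled library sizes. Principal components were taken over log2 CPM with a prior count of 2. In addition, each factor was compared with the mean of the factors of the other families, OSR (OSR1, OSR2), EGR1 and KLF (KLF2, KLF4), without Control, because the Control libraries stood apart. This contrast was chosen after seeing the data.

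28 lists of marker and pathway genes were tested with camera, which compares a list with the other genes, at a preset correlation of 0.01, two-sided, with adjustment over the 140 tests of 28 lists in 5 comparisons. The overexpressed genes were left out of each list. Camera with an estimated correlation and fry, which does not compare with other genes, served as alternatives. Overlap of calls was set beside independent calls and beside 20 simulations in which unchanged groups share the Control libraries. The samples, comparisons, tests, lists and alternatives, except those said to be chosen later, were fixed before the data were examined.

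The named genes follow a rule. For each comparison with Control it took the 5 overexpressed genes and the 6 largest rises and 6 largest falls among called genes with a symbol, a mean of at least 5 CPM over the 4 libraries and both factor libraries on the called side of both Control libraries. It also took the 3 called members with the smallest adjusted p from each of the 6 lists with most called members. Direct comparisons take up to 5 genes per factor by the same filters, and the 5 factors together the 6 genes with the largest mean absolute log2 fold change. All other named genes, among them SOX9, COL2A1, ACAN, COL9A1, MATN1, SOX6, IHH, COL10A1, RUNX2, SOST, TAGLN, CNN1, LDHA, NDRG1, HSPA5, ASNS, TNMD, DMP1, IBSP, KDR and KRT7, were chosen after their values were seen. Some of the genes chosen in this way are not reported here.

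The alternatives were DESeq2 1.42.0, median-of-ratios size factors, library totals alone, no low-count filter, a fit of the 2 groups compared only, the replicate number as a block, glmTreat against a 1.5-fold change, counts thinned to the smallest total and leaving out each library in turn. Tested on simulated data with set changes in 18979 genes, the edgeR test recovered 23.2% to 37.3% of 1.5-fold, 50% to 75.8% of 2-fold and 79.1% to 90.1% of 4-fold changes over the 7 comparisons, and 4.4% to 9.09% of its calls were false, so the calls hold somewhat more false ones than the 5% aimed at. In simulated lists, camera called a list of 30 raised genes, and 3 of 100 random lists lay under an unadjusted 0.05.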

Results

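RNA was sequenced from chick limb-bud mesenchymal cells taken at embryonic day 4.5 and grown as high-density droplet cultures for 5 days, a setting in which such cells form cartilage nodules among loose connective tissue and muscle cells. The cells carried an avian retroviral vector with the coding sequence of 1 of 5 transcription factors associated with connective tissue (OSR1, OSR2, EGR1, KLF2 or KLF4), or the vector without an insert (Control). There were 12 libraries in 6 groups of 2 replicates, and each RNA extract pooled 6 cultures. The total count per library was 51233721 and 59297870 in Control, 95874397 and 95309147 in OSR1 and 93496499 and 85072771 in OSR2. It was 106079374 and 90175670 in EGR1, 97733305 and 91316919 in KLF2 and 74139243 and 94891254 in KLF4. Of 21350 listed features, 18979 had enough counts to be tested. Values in parentheses after a gene are its log2 fold change over Control and the standard error (SE) of that change, from 2 against 2 libraries, unless another reference is named. CPM values are given as mean ± SD (n = 2), and the range in parentheses after an adjusted p without a library spans all alternatives tried for that result. The labels do not say whether replicates came from separate embryos or culture series, so p-values measure only the spread between these libraries.

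Each overexpressed gene had the largest rise over Control in its own libraries among genes with a mean of at least 5 CPM, as the plot of CPM per library shows. The zinc-finger gene OSR1 went from 4.92 ± 0.04 CPM in Control to 3200 ± 25 CPM in the OSR1 libraries (log2 fold change 9.34, SE 0.20, adjusted p = 2.1e-07). Its paralog OSR2 went from 11.8 ± 2.3 to 2100 ± 32 CPM in the OSR2 libraries (7.47, SE 0.16, adjusted p = 6.9e-08). EGR1, an immediate early transcription factor, went from 98.5 ± 7.3 to 8390 ± 1300 CPM (6.41, SE 0.15, adjusted p = 5.6e-08). The Krüppel-like factor KLF2 went from 33.6 ± 8.8 to 1700 ± 130 CPM (5.66, SE 0.28, adjusted p = 1.6e-05) and KLF4 from 17.9 ± 1.2 to 1230 ± 82 CPM (6.11, SE 0.11, adjusted p = 3.3e-09). The same genes also moved in libraries of other factors. OSR2 counts rose in OSR1 libraries (0.99, SE 0.16, adjusted p = 0.00093) and in EGR1 libraries (1.31, SE 0.16, adjusted p = 0.00041). KLF4 counts rose in OSR1 (0.72, SE 0.11, adjusted p = 0.00052) and OSR2 libraries (0.85, SE 0.11, adjusted p = 0.00017). The labels do not give the species of the inserts, and counts of an insert and of the cells' own gene were not separated.

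**Figure D1:**
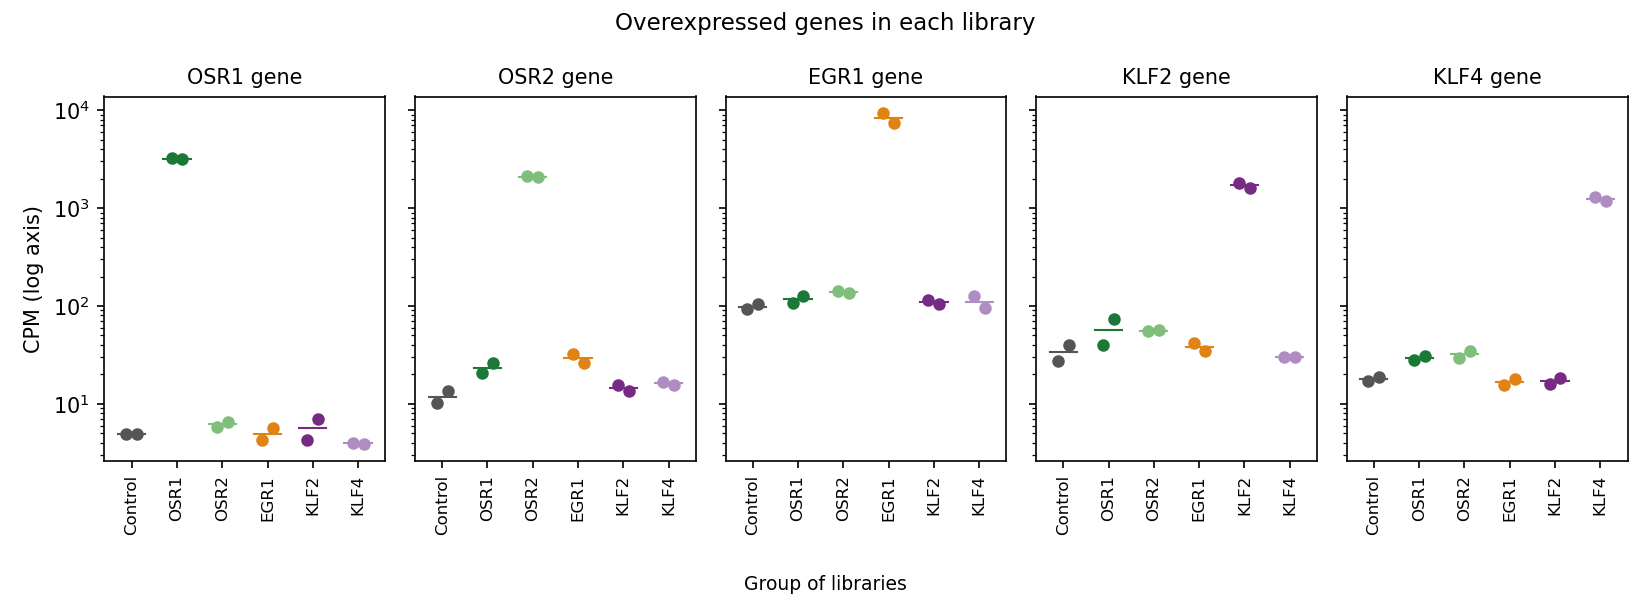
CPM (log axis) of the 5 overexpressed genes, 1 panel per gene, with 1 point per library in each of the 6 groups and a line at the group mean. Each gene is highest in the 2 libraries of its own vector, with KLF4 at 1230 ± 82 CPM against 17.9 ± 1.2 CPM in Control.

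The libraries separated into Control, OSR, EGR1 and KLF libraries. On the first principal component, which held 41.8% of the variance of log2 CPM, the Control libraries lay at -96.04 and -75.29 and the 10 factor libraries between -7.471 and 38.85. The second component (27%) held the OSR1 and OSR2 libraries between -46.44 and -39.83 and the KLF2 and KLF4 libraries between 22.09 and 46.96, and the third (8.01%) set the EGR1 libraries apart at 40.77 and 33.47. Replicates of a group correlated across genes with Pearson's r from 0.9887 in OSR1 to 0.9966 in KLF4. The 5.8S ribosomal RNA lay at 913.8 ± 116 CPM in Control and between 1630 ± 472 CPM in EGR1 and 3976 ± 2250 CPM in KLF4. Both Control libraries had fewer counts than any factor library.

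**Figure D2:**
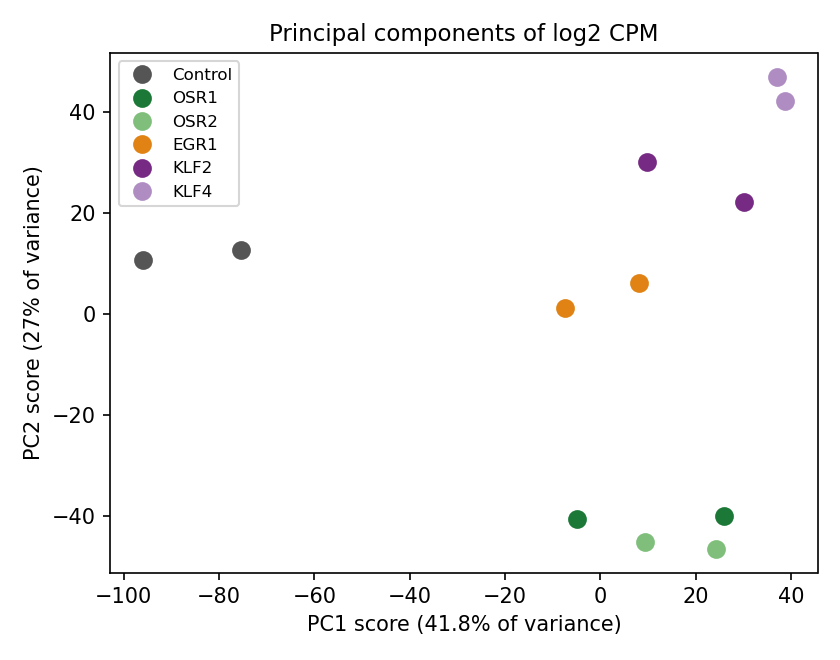
First (41.8% of variance) against second (27%) principal component of log2 CPM, 1 point per library, coloured by group. The Control libraries lie at -96.04 and -75.29 on the first component, below all 10 factor libraries.

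Counts of the retroviral entries gag, pol, env and ERVK-11 were lower with every insert than with the empty vector. Together they took 3.455 ± 0.0212% of counts in Control, 1.695 ± 0.0212% in OSR1, 1.825 ± 0.12% in OSR2, 1.76 ± 0.141% in EGR1, 0.8015 ± 0.0516% in KLF2 and 0.998 ± 0.017% in KLF4. The envelope gene env fell from 10020 ± 456 CPM to 1907 ± 58 CPM in KLF2 and 2182 ± 12 CPM in KLF4, with log2 fold changes of -1.16 in OSR1, -1.13 in OSR2, -1.22 in EGR1, -2.39 in KLF2 and -2.20 in KLF4 (SE 0.09, adjusted p between 4e-07 and 3.4e-05). The capsid gene gag fell less, with log2 fold changes of -0.83, -0.65, -0.60, -1.74 and -1.34 in the same order (SE 0.12). Other entries moved both ways. In KLF2 and KLF4, ERVK-25 was higher (0.51 and 0.64, SE 0.16, adjusted p = 0.02 and 0.0064) and ERVK-9 lower (-0.66 and -0.77, SE 0.07). Counts of these entries mix reads of the vector and of endogenous copies.

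The comparison of OSR1 with Control asks which genes change when this zinc-finger factor of irregular connective tissue is overexpressed. Cartilage genes fell. SOX9, the transcription factor that starts the cartilage programme, went from 369 ± 7.4 CPM in Control to 138 ± 24 CPM in OSR1 libraries (-1.42, SE 0.14, adjusted p = 5.4e-05). COL2A1, the main cartilage collagen, went from 4490 ± 860 to 1660 ± 56 CPM (-1.43, SE 0.18, adjusted p = 0.00021), and the proteoglycan core protein ACAN from 1850 ± 39 to 378 ± 96 CPM (-2.29, SE 0.18, adjusted p = 1.6e-05). Among genes with a mean of at least 5 CPM, the largest falls were those of GDF2, a BMP family ligand (-4.50, SE 0.16), the matrix gene VIT (-4.36, SE 0.29), the cartilage lectin CLEC3A (-4.06, SE 0.14), the anion exchanger SLC26A4 (-4.05, SE 0.20), GCNT1 (-3.97, SE 0.17) and NRIP3 (-3.85, SE 0.24). The largest rises besides OSR1 were those of EMILIN1, USP11, ELN, WBP1 and HIC1. ELN, which encodes elastin, rose by 3.11 (SE 0.25, adjusted p = 5.3e-05). The rises of EMILIN1 (3.35), USP11 (3.26), WBP1 (3.11) and HIC1 (3.05) depended on the library. Without OSR1 replicate 2 they were 1.61, 1.25, 1.55 and 1.71, and without OSR1 replicate 1 4.11, 4.07, 3.84 and 3.73. Without Control replicate 1 the adjusted p was 0.0613 for EMILIN1, 0.0938 for USP11 and 0.073 for WBP1, and without Control replicate 2 it was 0.0761 for USP11 and WBP1 was at 3.80. In a fit of the 4 libraries alone the adjusted p was 0.0653, 0.0813, 0.0711 and 0.054.

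The cartilage list fell (camera adjusted p = 6.1e-35, adjusted p = 0.054 with an estimated correlation), with 28 of 31 measured members lower and 3 not called (28 lower and 1 higher adjusted over the list alone). HAPLN1 (-2.61, SE 0.13), PAPSS2 (-2.31, SE 0.11) and LECT1 (-2.11, SE 0.12) were among the called members. COL9A1 (-3.12, SE 0.22), MATN1 (-2.65, SE 0.24) and SOX6 (-2.40, SE 0.16) fell as well. The hypertrophic cartilage and bone list had 4 of 24 measured members higher, 11 lower and 9 not called (4 and 11 adjusted over the list alone, camera adjusted p = 0.059). It was lower at adjusted p = 0.012 without Control replicate 1 and 0.042 without OSR1 replicate 2 (0.0038 to 0.36). Its called members included IHH (-2.15, SE 0.41), COL10A1 (-1.58, SE 0.18) and RUNX2 (-1.11, SE 0.09), markers of maturing cartilage, which fell, and the sclerostin gene SOST (2.11, SE 0.19), which rose. FBLN5 (1.63, SE 0.07), COL3A1 (1.14, SE 0.08) and MFAP5 (1.10, SE 0.09) of loose connective tissue rose, and so did TAGLN (2.19, SE 0.22) and CNN1 (1.96, SE 0.14) of smooth muscle. The skeletal muscle list gave 21 of 51 measured members higher, 8 lower and 22 not called (21 and 9 adjusted over the list alone, camera adjusted p = 0.2), including MYL4 (1.39, SE 0.13) and MYH15 (0.80, SE 0.09), which rose, and TNNT3 (-1.37, SE 0.10), which fell.

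FGF and MAPK feedback genes rose as a list (camera adjusted p = 0.047, adjusted p = 0.36 with an estimated correlation), with 13 of 26 measured members higher, 5 lower and 8 not called (13 and 5 adjusted over the list alone). Called members included SPRY2 (1.37, SE 0.12) and ETV5 (1.46, SE 0.19). That call was lost at adjusted p = 0.055 without Control replicate 1, 0.053 without Control replicate 2 and 0.081 without OSR1 replicate 2 (0.0011 to 0.36), and with the block at 0.055. The WNT signalling list gave 22 of 44 measured members higher, 11 lower and 11 not called (23 and 11 adjusted over the list alone, camera adjusted p = 0.053), with FZD4 (1.71, SE 0.09), WNT11 (1.34, SE 0.11) and RNF43 (-1.89, SE 0.19) among the called members. It was called at adjusted p = 0.024 without OSR1 replicate 1 (0.0038 to 0.47) and with the replicate number as a block (0.049). Notch signalling had 12 of 22 measured members higher, 2 lower and 8 not called (12 and 2 adjusted over the list alone, camera adjusted p = 0.08) and was called at adjusted p = 0.046 without Control replicate 2 (0.01 to 0.5). PTCH1, the Hedgehog receptor and target, fell by 1.64 on the log2 scale (SE 0.09). The Hedgehog list had 7 of 14 measured members higher, 4 lower and 3 not called (7 and 4 adjusted over the list alone, camera adjusted p = 0.7). The guidance genes EFNB2 (1.56, SE 0.09) and NTNG1 (1.18, SE 0.08) rose and the chemokine CXCL14 (-1.31, SE 0.08) fell. The limb patterning transcription factor list had 21 of 50 measured members higher, 2 lower and 27 not called (21 and 2 adjusted over the list alone). As a list, limb patterning transcription factor genes rose (camera adjusted p = 0.00045, 0.36 with an estimated correlation).

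Of 18979 genes, 9688 were called, 5381 higher and 4307 lower, of which 1943 and 1181 changed at least 2-fold. Without Control replicate 1 the count was 5807. Measured against the EGR1, KLF2 and KLF4 libraries instead of Control, 3813 genes were called, and 2026 genes were called in the same direction in both and 363 in opposite ones. In that contrast the cartilage list fell (25 of 31 lower, adjusted p = 2.1e-44, 0.034 with an estimated correlation). SOX9 was at -1.42, SE 0.12, adjusted p = 3.3e-05. The hypertrophic list was lower too (16 of 24 lower and 3 higher, adjusted p = 2.1e-10, 0.034 with an estimated correlation). Skeletal muscle genes were higher (28 of 51, adjusted p = 3.9e-10, 0.045 with an estimated correlation). Against Control, KLF2 and KLF4 raised hypertrophic and lowered muscle genes.

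OSR2, the paralog of OSR1, was compared with Control for the same question. Cartilage genes fell with it too. SOX9 stood at 99.6 ± 8.5 CPM against 369 ± 7.4 CPM in Control (-1.89, SE 0.14, adjusted p = 7.1e-06). COL2A1 stood at 1080 ± 54 against 4490 ± 860 CPM (-2.06, SE 0.18, adjusted p = 1.9e-05) and ACAN at 264 ± 11 against 1850 ± 39 CPM (-2.81, SE 0.18, adjusted p = 3.8e-06). The largest falls were those of GDF2 (-5.94, SE 0.19), VIT (-5.26, SE 0.32), NRIP3 (-5.15, SE 0.25), FGFBP2 (-5.14, SE 0.31), C2orf82 (-4.76, SE 0.36) and GDF10 (-4.65, SE 0.13). Besides OSR2 itself, the largest rises were those of the elastin gene ELN (3.49, SE 0.25), EMILIN1 (3.25, SE 0.71), the tubulin-binding gene TPPP3 (3.19, SE 0.20), the transcription factor gene HIC1 (3.16, SE 0.61) and the axon guidance ligand NTN1 (3.12, SE 0.34). The EMILIN1 estimate was 2.90 without Control replicate 1 (adjusted p = 0.0626), with adjusted p from 3.6e-05 to 0.063.

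The cartilage list had 28 of 31 measured members lower and 3 not called (28 lower and 1 higher adjusted over the list alone). HAPLN1 (-3.13, SE 0.13), PAPSS2 (-2.74, SE 0.11) and LECT1 (-2.61, SE 0.12) were among those called, and the list fell (camera adjusted p = 4.9e-45, adjusted p = 0.035 with an estimated correlation). COL9A1 (-4.16, SE 0.22), MATN1 (-4.14, SE 0.24) and SOX6 (-2.82, SE 0.16) also fell. Hypertrophic cartilage and bone genes fell as a list (camera adjusted p = 0.029, adjusted p = 0.36 with an estimated correlation), with 5 of 24 measured members higher, 11 lower and 8 not called (5 and 11 adjusted over the list alone). Called members included COL10A1 (-1.86, SE 0.18), RUNX2 (-1.49, SE 0.09) and SOST (2.50, SE 0.19). The hypertrophic call ended at adjusted p = 0.051 without Control replicate 2 and 0.071 without OSR2 replicate 1 (0.0017 to 0.36). FBLN5 (1.93, SE 0.07), COL3A1 (1.27, SE 0.08) and MFAP5 (1.31, SE 0.09) of connective tissue, TAGLN (2.41, SE 0.22) and CNN1 (2.25, SE 0.14) of smooth muscle and the guidance genes NTNG1 (1.40, SE 0.08) and EFNB2 (1.66, SE 0.09) rose. The chemokine CXCL14 (-1.18, SE 0.08) fell. Skeletal muscle genes had 20 of 51 measured members higher, 9 lower and 22 not called (20 and 9 adjusted over the list alone, camera adjusted p = 0.17), among them MYL4 (1.52, SE 0.13) and MYH15 (0.95, SE 0.09) higher and TNNT3 (-1.35, SE 0.10) lower.

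The WNT signalling list had 21 of 44 measured members higher, 10 lower and 13 not called (21 and 10 adjusted over the list alone). FZD4 (1.82, SE 0.09), WNT11 (1.59, SE 0.11) and RNF43 (-2.19, SE 0.20) were among those called, and the list rose (camera adjusted p = 0.047, adjusted p = 0.46 with an estimated correlation). That WNT call ended at adjusted p = 0.066 without Control replicate 1 and 0.054 without Control replicate 2 (0.0022 to 0.46). The limb patterning transcription factor list rose (camera adjusted p = 0.0018, adjusted p = 0.38 with an estimated correlation), with 23 of 50 measured members higher, 5 lower and 22 not called (23 and 5 adjusted over the list alone). The BMP antagonist GREM1 (1.17, SE 0.11), the ligand GDF6 (1.64, SE 0.19) and the growth factor FGF7 (2.11, SE 0.18) rose and the Hedgehog receptor PTCH1 (-2.05, SE 0.09) fell.

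The test called 9853 genes, 5488 higher and 4365 lower, with 2090 and 1334 changed at least 2-fold, and 6362 genes without Control replicate 1. Against the EGR1, KLF2 and KLF4 libraries, 4686 genes were called, 2668 of them in the direction seen against Control and 397 in the opposite one. There the cartilage list fell (27 of 31 lower, adjusted p = 3e-58, adjusted p = 0.025 with an estimated correlation), as did the hypertrophic list (17 of 24 lower and 4 higher, adjusted p = 1e-09, adjusted p = 0.041 with an estimated correlation). The smooth muscle list rose (15 of 24 higher, adjusted p = 2e-07, adjusted p = 0.43 with an estimated correlation), and so did the skeletal muscle list (30 of 51 higher and 1 lower, adjusted p = 6e-09, adjusted p = 0.06 with an estimated correlation).

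OSR1 and OSR2 libraries were then compared with each other. Only the overexpressed genes themselves were called over all 18979 genes, OSR1 higher in OSR1 libraries (log2 OSR1 over OSR2 9.01, SE 0.19, adjusted p = 2.6e-07) and OSR2 higher in OSR2 libraries (-6.48, SE 0.16, adjusted p = 2.6e-07). 729 genes had an unadjusted p under 0.05, fewer than the 5% chance would give. DESeq2 called 35 genes, edgeR 103 without OSR1 replicate 1, 8 without OSR1 replicate 2, and 5 with the replicate number as a block. As a list, cartilage genes were higher in OSR1 than in OSR2 libraries. Of 31 measured cartilage genes, 29 had a higher estimate in OSR1, 20 lay under an unadjusted p of 0.05, and 19 were higher adjusted over the list alone (median log2 difference 0.42, camera adjusted p = 9.3e-40, adjusted p = 0.058 with an estimated correlation). None of the 31 passed over all genes in edgeR, and 8 did in DESeq2, 1 without OSR1 replicate 1 and 3 without OSR1 replicate 2. The matrilin gene MATN1 differed by 1.49, SE 0.24 (adjusted p = 0.55, and 0.0274 with the block) and COL9A1 by 1.04, SE 0.22 (adjusted p = 0.92). Without OSR1 replicate 2 they differed by 1.81 and 1.38 (adjusted p = 0.00648 for each). For MATN1 the alternatives gave an adjusted p of 1.2e-08 to 1 and for COL9A1 of 0.0005 to 1. Of the interferon, fibrillar, smooth muscle, retinoic acid and cell cycle lists, 0 members were called, and 0, 1, 0, 0 and 0 adjusted over the list alone. Camera gave these lists adjusted p = 0.00012, 0.00026, 0.003, 0.011 and 0.017 (0.058, 0.47, 0.77, 0.26 and 0.77 with an estimated correlation). The first 4 were lower in OSR1 and the cell cycle list higher. Genes called in the same direction in both comparisons with Control numbered 8789, 4915 higher and 3874 lower, and 5308 without Control replicate 1. Independent calls would give 1556 and 990.6. Across genes, log2 fold changes correlated with Pearson's r = 0.922, where unchanged groups simulated against the same Control libraries gave 0.552, and their covariance was 0.766 against 0.0513 simulated. The 2 Control libraries could not be split between the comparisons, so part of the excess may come from shared controls.

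EGR1, a zinc-finger factor linked to tendon, was compared with Control. TNMD (0.90, SE 0.09), the tendon gene tenomodulin, went from 112 ± 8 CPM in Control to 209 ± 16 CPM in EGR1 libraries (adjusted p = 0.00012). DMP1, an acidic matrix phosphoprotein of bone, went from 1.65 ± 0.025 to 8.5 ± 0.87 CPM (2.36, SE 0.18, adjusted p = 3.6e-05), and the matrix phosphoprotein SPP1 (1.20, SE 0.14) rose too. The largest rises besides EGR1 were those of the cadherin CELSR2 (3.21, SE 0.54), EMILIN1 (2.59, SE 0.71), the glutamine synthetase gene GLUL (2.50, SE 0.09), the transcription factor ZBTB16 (2.50, SE 0.23) and CLIC3 (2.45, SE 0.23). The largest falls were those of the carbonic anhydrase CA4 (-3.02, SE 0.19), CHAC1 (-2.84, SE 0.81), DEFB125 (-2.59, SE 0.61), the anion exchanger SLC26A4 (-2.37, SE 0.18), TAF4B (-2.29, SE 0.13) and the methionine enzyme MAT1A (-2.27, SE 0.15). For EMILIN1 the estimate was 2.25 without Control replicate 1 (adjusted p = 0.132), 3.08 without Control replicate 2 (adjusted p = 0.06) and 2.19 without EGR1 replicate 1 (adjusted p = 0.105), with adjusted p from 0.00082 to 0.13. CHAC1 stood at -2.97 without Control replicate 1 (adjusted p = 0.076), -2.68 without Control replicate 2 (adjusted p = 0.0845), -2.36 without EGR1 replicate 1 (adjusted p = 0.168) and -3.54 without EGR1 replicate 2 (adjusted p = 0.0566), with adjusted p from 0.00073 to 0.17. DEFB125 stood at -2.52 without Control replicate 1 (adjusted p = 0.0522), -2.74 without EGR1 replicate 1 (adjusted p = 0.0701) and -2.45 without EGR1 replicate 2 (adjusted p = 0.0684), with adjusted p from 8.2e-05 to 0.07. Against the mean of the other 4 factors, TNMD was higher by 0.37, SE 0.07, adjusted p = 0.0042 and the tendon matrix gene THBS4 by 1.56, SE 0.09, adjusted p = 1.9e-06. The tendon list was not called there (6 of 23 higher and 5 lower, adjusted p = 0.82). In the same contrast GLUL (0.04, SE 0.07, adjusted p = 0.81) and CA4 (0.01, SE 0.15, adjusted p = 0.99) were not called, and SLC26A4 was higher (0.94, SE 0.15, adjusted p = 0.0014).

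Cartilage genes had 3 of 31 measured members higher, 9 lower and 19 not called (3 and 7 adjusted over the list alone, camera adjusted p = 0.11). The list was lower at adjusted p = 0.02 without EGR1 replicate 1 (0.02 to 0.59) and with the replicate number as a block (adjusted p = 0.049). SOX9 stood at 438 ± 68 CPM against 369 ± 7.4 CPM in Control (0.25, SE 0.14, adjusted p = 0.18) and ACAN at 1680 ± 280 against 1850 ± 39 CPM (adjusted p = 0.56). COL2A1 was higher by 0.58, SE 0.18 (adjusted p = 0.026), but its estimate was 0.40 without Control replicate 1 (adjusted p = 0.183) and 0.37 without EGR1 replicate 1 (adjusted p = 0.198), with adjusted p from 0.0055 to 0.79. Against the mean of the other 4 factors, lowered most by OSR1 and OSR2, 25 of 31 cartilage genes were higher and 6 not called (28 and 1 adjusted over the list alone, adjusted p = 9.6e-75, 0.025 with an estimated correlation), with SOX9 at 1.14, SE 0.11, adjusted p = 7.2e-05. The leucine-rich repeat proteoglycan EPYC (-1.38, SE 0.18) fell. The matrix genes FBLN5 (0.72, SE 0.07), COL6A2 (0.71, SE 0.09) and FN1 (1.37, SE 0.17) rose over Control. The fibrillar and loose connective tissue list was lower than in the other 4 factors (13 of 35 lower and 2 higher, adjusted p = 2e-07, adjusted p = 0.29 with an estimated correlation). Skeletal muscle genes had 15 of 51 measured members higher, 12 lower and 24 not called (16 and 12 adjusted over the list alone, camera adjusted p = 0.62), including TNNT3 (-1.42, SE 0.10) and MYOM2 (-0.75, SE 0.09) lower and MYL4 (1.15, SE 0.13) higher. Against the other 4 factors this list was higher (10 of 51, adjusted p = 0.002, 0.37 with an estimated correlation). The interferon response list gave 13 of 43 measured members higher, 13 lower and 17 not called (14 and 14 adjusted over the list alone, camera adjusted p = 0.91), with LY6E (1.02, SE 0.08) and IFITM5 (1.25, SE 0.18) higher and HELZ2 (-1.08, SE 0.13) lower.

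Notch signalling genes rose as a list (camera adjusted p = 0.021, adjusted p = 0.43 with an estimated correlation), with 13 of 22 measured members higher, 3 lower and 6 not called (13 and 4 adjusted over the list alone). Called members included NOTCH1 (1.30, SE 0.24) and HEYL (1.26, SE 0.20). The Hedgehog signalling list rose (camera adjusted p = 0.028, adjusted p = 0.47 with an estimated correlation), with 8 of 14 measured members higher, 1 lower and 5 not called (8 and 1 adjusted over the list alone). GLI2 (1.08, SE 0.17) was among the called members. Without Control replicate 2 the Hedgehog list was at adjusted p = 0.057 (0.0068 to 0.47). The guidance genes NTN4 (1.21, SE 0.11) and EFNB2 (1.07, SE 0.09) rose and CXCL14 (-1.73, SE 0.08) fell. The limb patterning list had 19 of 50 measured members higher, 6 lower and 25 not called (19 and 6 adjusted over the list alone, camera adjusted p = 0.067), with the limb mesenchyme factors PRRX1 (0.81, SE 0.09), EMX2 (0.92, SE 0.11) and MEIS1 (0.73, SE 0.09) higher. Against the other 4 factors it was lower (6 lower and 2 higher, adjusted p = 0.014, 0.75 with an estimated correlation), as was PRRX1 (-0.73, adjusted p = 0.00011).

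Cell cycle genes rose as a list (camera adjusted p = 0.043, adjusted p = 0.47 with an estimated correlation), with 19 of 44 measured members higher, 2 lower and 23 not called (19 and 2 adjusted over the list alone). Called members included MCM5 (1.31, SE 0.20) and TYMS (-0.88, SE 0.12). The cell cycle call ended at adjusted p = 0.057 without Control replicate 2 and 0.11 without EGR1 replicate 2 (0.0043 to 0.47), and with median-of-ratios scaling at 0.052. Called genes numbered 8559, 4675 higher and 3884 lower, with 1483 and 866 changed at least 2-fold. With library totals alone the called genes turned from 54.6% to 45.2% higher. The count was 4698 without Control replicate 1 and 4597 without EGR1 replicate 1. Against the other 4 factors 2374 genes were called, 584 of them in the direction seen against Control and 616 in the opposite direction.

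KLF2, a Krüppel-like factor known from endothelial cells, was compared with Control. The largest rises besides KLF2 were those of NTN3, a netrin of axon guidance (4.17, SE 0.21, adjusted p = 4.7e-06), the scavenger receptors SCARA5 (3.81, SE 0.28) and SCARA3 (3.35, SE 0.19), FCGBP (3.77, SE 0.25) and the homeobox gene DLX3 (3.40, SE 0.31). The largest falls were those of the carbonic anhydrase CA4 (-3.63, SE 0.19), CHAC1 (-3.38, SE 0.81), SEZ6L (-3.22, SE 0.39), SPHKAP (-2.63, SE 0.19), the lactate transporter SLC16A3 (-2.57, SE 0.13) and EMB (-2.54, SE 0.20). CHAC1 was at -2.98 without KLF2 replicate 1 (adjusted p = 0.0907) and -3.98 without KLF2 replicate 2 (adjusted p = 0.0428), with adjusted p from 0.0006 to 0.091, and SEZ6L at -4.10 without KLF2 replicate 1. IBSP, the bone sialoprotein gene, rose from 0.615 ± 0.18 CPM in Control to 4.16 ± 1.8 CPM in KLF2 libraries (2.75, SE 0.35, adjusted p = 2e-04). The endothelial receptor KDR went from 13.4 ± 0.068 to 25.7 ± 3.3 CPM (0.94, SE 0.10, adjusted p = 5.9e-05).

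The cartilage list had 1 of 31 measured members higher, 20 lower and 10 not called (1 and 20 adjusted over the list alone). MATN1 (-1.36, SE 0.24) and COL9A1 (-1.06, SE 0.22) were among those called, and the list fell (camera adjusted p = 9.8e-07, adjusted p = 0.33 with an estimated correlation). SOX9 (-0.30, SE 0.14, adjusted p = 0.1) and COL2A1 (0.03, SE 0.18, adjusted p = 0.9) were not called. Against the OSR1, OSR2 and EGR1 libraries the same list was higher (21 of 31 higher and 1 lower, adjusted p = 7.4e-23, 0.073 with an estimated correlation), as it fell further in OSR1 and OSR2 (medians -1.76 and -2.29 against -0.64). Hypertrophic cartilage and bone genes rose as a list (camera adjusted p = 0.028, adjusted p = 0.33 with an estimated correlation), with 14 of 24 measured members higher, 4 lower and 6 not called (14 and 4 adjusted over the list alone). Called members included IBSP (2.75, SE 0.35), COL10A1 (0.84, SE 0.17) and DLX5 (0.80, SE 0.16). The skeletal muscle list had 11 of 51 measured members higher, 24 lower and 16 not called (11 and 26 adjusted over the list alone). TNNT3 (-1.42, SE 0.10), KLHL31 (-1.53, SE 0.13) and MYOM2 (-1.0, SE 0.09) were among those called, and the list fell (camera adjusted p = 0.022, adjusted p = 0.36 with an estimated correlation). CKMT2 (-2.07, SE 0.29) of muscle energy supply and MYBPC1 (-0.67, SE 0.11) and ACTN2 (-0.82, SE 0.08) of the contractile apparatus fell as well. That muscle call ended at adjusted p = 0.052 without Control replicate 2 and 0.094 without KLF2 replicate 2 (0.0024 to 0.36). Against the OSR1, OSR2 and EGR1 libraries the muscle list was lower (26 of 51, adjusted p = 1.6e-10, 0.045 with an estimated correlation). The endothelial list had 10 of 28 measured members higher, 5 lower and 13 not called (10 and 5 adjusted over the list alone, camera adjusted p = 0.2), with TIE1 (3.46, SE 0.47) and CLDN5 (1.58, SE 0.10) among the higher genes.

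The WNT signalling list had 24 of 44 measured members higher, 6 lower and 14 not called (27 and 9 adjusted over the list alone). WNT9A (1.12, SE 0.08), FZD4 (0.94, SE 0.09) and AXIN2 (0.90, SE 0.09) were among those called, and the list rose (camera adjusted p = 0.015, adjusted p = 0.42 with an estimated correlation). Notch signalling genes rose as a list (camera adjusted p = 3e-04, adjusted p = 0.33 with an estimated correlation), with 15 of 22 measured members higher, 3 lower and 4 not called (15 and 3 adjusted over the list alone). Called members included NOTCH1 (1.43, SE 0.24), HES1 (1.62, SE 0.29) and HEYL (3.07, SE 0.20). Limb patterning transcription factor genes rose as a list (camera adjusted p = 0.0072, adjusted p = 0.43 with an estimated correlation), with 22 of 50 measured members higher, 6 lower and 22 not called (22 and 6 adjusted over the list alone). Called members included PRRX1 (1.48, SE 0.09), PRRX2 (1.51, SE 0.14) and TBX3 (1.20, SE 0.12). The limb patterning call ended at adjusted p = 0.075 without KLF2 replicate 2 (0.00075 to 0.43). Hedgehog genes had 6 of 14 measured members higher, 2 lower and 6 not called (6 and 2 adjusted over the list alone, camera adjusted p = 0.095) and were called at adjusted p = 0.021 without KLF2 replicate 2 (0.021 to 0.54). The BMP antagonist GREM1 (-1.08, SE 0.11) and the chemokine CXCL14 (-1.02, SE 0.08) fell, and the ligand BMP5 (1.18, SE 0.09), the guidance receptor EPHB1 (2.01, SE 0.14) and the vitamin A transporter STRA6 (0.98, SE 0.14) rose. Interferon response genes had 16 of 43 measured members higher, 14 lower and 13 not called (17 and 14 adjusted over the list alone, camera adjusted p = 0.91), with IFITM5 (1.55, SE 0.18) and IRF9 (1.66, SE 0.27) higher and the RNA sensor TLR3 (-2.12, SE 0.24) lower.

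The cell cycle list rose (camera adjusted p = 0.0078, adjusted p = 0.41 with an estimated correlation), with 22 of 44 measured members higher, 3 lower and 19 not called (22 and 3 adjusted over the list alone). MCM5 (1.30, SE 0.20) and TYMS (-0.93, SE 0.12) were among the called members. That list was not called at adjusted p = 0.093 without KLF2 replicate 2 (0.00048 to 0.41). In all, 9801 genes were called, 5342 higher and 4459 lower, with 2012 and 1269 changed at least 2-fold, and 6303 without Control replicate 1. The share of higher genes among those called went from 54.5% to 49.8% with library totals alone. Against the OSR1, OSR2 and EGR1 libraries 2888 genes were called, 1508 of them in the direction seen against Control and 387 in the opposite one.

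KLF4, known from epidermal differentiation, was compared with Control. KRT7, a keratin of simple epithelia, went from 67.3 ± 4.3 CPM in Control to 383 ± 38 CPM (2.51, SE 0.27, adjusted p = 0.00023). KRT19 (2.37, SE 0.40), GRHL1 (1.54, SE 0.22) and TP63 (0.84, SE 0.15) rose with it, while the epithelial adhesion gene EPCAM was not called (0.46, SE 0.49, adjusted p = 0.45). The largest rises besides KLF4 were those of the scavenger receptor SCARA5 (4.99, SE 0.28), the keratin KRT6A (4.60, SE 0.72), the complement regulator CD55 (4.44, SE 0.23), FCGBP (4.36, SE 0.25) and PSCA (4.25, SE 0.23). IBSP went from 0.615 ± 0.18 to 11.3 ± 0.83 CPM (4.19, SE 0.34, adjusted p = 1.4e-05) and the endothelial receptor KDR from 13.4 ± 0.068 to 107 ± 1.9 CPM (3.00, SE 0.10, adjusted p = 1.2e-07). The largest falls were those of CA4 (-3.86, SE 0.19), CHAC1 (-3.36, SE 0.82), ADPRHL1 (-3.29, SE 0.12), SLC26A4 (-2.80, SE 0.19), RXFP1 (-2.76, SE 0.16) and MAT1A (-2.67, SE 0.15). CHAC1 was at -3.67 without KLF4 replicate 1 (adjusted p = 0.0557) and -3.10 without KLF4 replicate 2 (adjusted p = 0.0851), with adjusted p from 1.2e-05 to 0.085.

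The epithelial and epidermal list rose (camera adjusted p = 3e-04, adjusted p = 0.52 with an estimated correlation), with 23 of 42 measured members higher, 2 lower and 17 not called (23 and 2 adjusted over the list alone). KRT7 (2.51, SE 0.27) and KRT19 (2.37, SE 0.40) were among the called members. Against the OSR1, OSR2 and EGR1 libraries 16 of 42 epithelial genes were higher and 3 lower (adjusted p = 3.6e-06, adjusted p = 0.75 with an estimated correlation). The endothelial list had 13 of 28 measured members higher, 4 lower and 11 not called (13 and 4 adjusted over the list alone). KDR (3.00, SE 0.10), TIE1 (4.39, SE 0.47) and CLDN5 (1.80, SE 0.10) were among those called, and the list rose (camera adjusted p = 0.0076, adjusted p = 0.2 with an estimated correlation). Adipocyte and lipid storage genes rose as a list (camera adjusted p = 0.032, adjusted p = 0.33 with an estimated correlation), with 12 of 21 measured members higher, 3 lower and 6 not called (12 and 3 adjusted over the list alone). The skeletal muscle list fell (camera adjusted p = 1.9e-06, adjusted p = 0.14 with an estimated correlation), with 8 of 51 measured members higher, 32 lower and 11 not called (10 and 32 adjusted over the list alone). TNNT3 (-1.73, SE 0.11), MYOM2 (-1.19, SE 0.09) and TNNT2 (-1.01, SE 0.09) were among the called members. CKMT2 (-2.56, SE 0.31) and MYBPC1 (-1.12, SE 0.11) of muscle energy supply and contraction and the myogenic factor MYOD1 (-1.06, SE 0.24) fell too. In the contrast with OSR1, OSR2 and EGR1, 37 of 51 muscle genes were lower (adjusted p = 1.3e-17, 0.025 with an estimated correlation). Cartilage genes fell as a list (camera adjusted p = 8.6e-05, adjusted p = 0.36 with an estimated correlation), with 4 of 31 measured members higher, 19 lower and 8 not called (7 and 19 adjusted over the list alone). Called members included MATN1 (-1.55, SE 0.24) and COL9A1 (-1.17, SE 0.22). SOX9 (0.06, SE 0.14, adjusted p = 0.74) and COL2A1 (0.02, SE 0.18, adjusted p = 0.93) were not called. Given the OSR falls, the cartilage list was higher against OSR1, OSR2 and EGR1 (23 of 31 higher and 2 lower, adjusted p = 3.9e-16, 0.15 with an estimated correlation). The hypertrophic cartilage and bone list rose (camera adjusted p = 0.0015, adjusted p = 0.2 with an estimated correlation), with 16 of 24 measured members higher, 6 lower and 2 not called (18 and 6 adjusted over the list alone). IBSP (4.19, SE 0.34) and DLX5 (0.97, SE 0.16) were among the called members. The matrix remodelling list had 18 of 33 measured members higher, 10 lower and 5 not called (18 and 11 adjusted over the list alone, camera adjusted p = 0.07) and was called at adjusted p = 0.044 without KLF4 replicate 1 and 0.044 without KLF4 replicate 2 (0.011 to 0.53). Its protease genes ADAMTS15 (2.16, SE 0.14) and MMP9 (2.56, SE 0.21) and the inhibitor TIMP2 (1.98, SE 0.16) were higher.

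The WNT signalling list rose (camera adjusted p = 0.004, adjusted p = 0.36 with an estimated correlation), with 23 of 44 measured members higher, 7 lower and 14 not called (23 and 7 adjusted over the list alone). TNFRSF19 (1.29, SE 0.10), WNT2B (3.21, SE 0.25) and WNT9A (0.99, SE 0.08) were among the called members. The Notch signalling list had 14 of 22 measured members higher, 3 lower and 5 not called (14 and 3 adjusted over the list alone). NOTCH1 (1.51, SE 0.24), HES1 (1.77, SE 0.29) and HEYL (3.50, SE 0.20) were among those called, and the list rose (camera adjusted p = 0.0023, adjusted p = 0.36 with an estimated correlation). Limb patterning factors had 19 of 50 measured members higher, 9 lower and 22 not called (19 and 9 adjusted over the list alone, camera adjusted p = 0.064), with PRRX1 (1.52, SE 0.09) and TBX3 (1.32, SE 0.12) higher and ALX1 (-2.24, SE 0.21) lower. The list was called at adjusted p = 0.04 without KLF4 replicate 2 (0.0061 to 0.52). BMP and GDF genes had 18 of 31 measured members higher, 8 lower and 5 not called (18 and 8 adjusted over the list alone, camera adjusted p = 0.05) and were called at adjusted p = 0.041 without KLF4 replicate 1 and 0.03 without KLF4 replicate 2 (0.00087 to 0.36). Of these, BMP5 (2.14, SE 0.09) and ID1 (3.84, SE 0.55) were higher and GREM1 (-1.33, SE 0.11) lower. The guidance genes NTN3 (3.92, SE 0.21), UNC5B (2.0, SE 0.13) and EPHB1 (2.19, SE 0.14) and the vitamin A transporter STRA6 (1.98, SE 0.14) rose.

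The test called 10284 genes for KLF4, 5452 higher and 4832 lower, with 2477 and 1512 changed at least 2-fold. The called genes were 53% higher ones, and 49.1% with library totals alone. Against the OSR1, OSR2 and EGR1 libraries 5041 genes were called, 2979 of them in the direction seen against Control and 487 in the opposite one.

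KLF2 and KLF4 libraries were compared with each other. Higher in KLF4 were STMN2, a microtubule regulator of neurons (log2 KLF2 over KLF4 -2.66, SE 0.15, adjusted p = 2.1e-05), PI16 of fibroblasts (-2.37, SE 0.12, adjusted p = 8.5e-06), S100A4 (-2.27, SE 0.16, adjusted p = 1e-04), and the endothelial genes KDR (-2.06, SE 0.10, adjusted p = 5.7e-06) and EMCN (-1.53, SE 0.20, adjusted p = 0.0034). Besides KLF2 (5.82, SE 0.28), PODN, a small proteoglycan, was higher in KLF2 (0.85, SE 0.10, adjusted p = 0.0022), as was ERVK-8 (0.79, SE 0.10, adjusted p = 0.0025, and 0.0624 in a fit of the 4 libraries alone). GCHFR (0.96, SE 0.14) also ranked high in KLF2, at 0.94 without KLF4 replicate 1 (adjusted p = 0.0956) and 0.99 without KLF4 replicate 2 (adjusted p = 0.0593), with adjusted p from 4.4e-07 to 0.3. CHRNA2 (0.93, SE 0.21) was at 0.70 without KLF2 replicate 1 (adjusted p = 0.162), 1.09 without KLF2 replicate 2 (adjusted p = 0.0784), 0.77 without KLF4 replicate 1 (adjusted p = 0.409) and 1.11 without KLF4 replicate 2 (adjusted p = 0.135), with adjusted p from 0.0049 to 1. SCEL (-2.47, SE 0.36), higher in KLF4, was at -2.57 without KLF2 replicate 1 (adjusted p = 0.0638), -2.42 without KLF2 replicate 2 (adjusted p = 0.131), -2.38 without KLF4 replicate 1 (adjusted p = 0.109) and -2.56 without KLF4 replicate 2 (adjusted p = 0.0619), with adjusted p from 5.1e-13 to 0.13. The KLF4 gene itself differed by -6.17, SE 0.11. Skeletal muscle genes were higher in KLF2, with 8 of 51 measured members higher and 43 not called (16 higher adjusted over the list alone, camera adjusted p = 1.1e-11, adjusted p = 0.058 with an estimated correlation). Epithelial and epidermal genes were lower in KLF2, with 7 of 42 measured members lower and 35 not called (20 lower adjusted over the list alone, camera adjusted p = 4e-16, adjusted p = 0.42 with an estimated correlation). Endothelial genes were lower as well, with 5 of 28 measured members lower and 23 not called (8 lower and 2 higher adjusted over the list alone, camera adjusted p = 2e-05, adjusted p = 0.058 with an estimated correlation). The neural crest, glial, neuronal and pigment list was lower too, with 5 of 25 measured members lower and 20 not called (8 lower adjusted over the list alone, camera adjusted p = 3.3e-06, adjusted p = 0.16 with an estimated correlation). Retinoic acid pathway genes were lower in KLF2 than in KLF4, with 4 of 17 measured members lower and 13 not called (5 lower adjusted over the list alone, camera adjusted p = 0.00021, adjusted p = 0.12 with an estimated correlation). In this comparison 505 genes were called, 128 higher and 377 lower in KLF2, and at least 2-fold 19 and 182. That count was 169 without KLF2 replicate 2, 93 without KLF4 replicate 1 and 158 without KLF4 replicate 2. Genes called in the same direction against Control by both factors numbered 8380, 4586 higher and 3794 lower, and 10 were called in opposite directions, where independent calls would give 1535 higher and 1135 lower. The shared count was 5262 without Control replicate 1. Log2 fold changes correlated across genes with r = 0.915 against 0.55 simulated with shared Control libraries, and their covariance was 0.802 against 0.0516. The 2 Control libraries could not be split here either, so part of the excess may come from shared controls.

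Across all 5 factors, 5303 genes were called in the same direction against Control, 3124 higher and 2179 lower, which is 37.6% of the 14103 genes called in at least 1 comparison. Independent calls would give 30.99 and 12.126, and 20 simulations of unchanged groups with shared controls at most 0. Neither covers shared controls where many genes are called, so part of the excess may come from them. Without Control replicate 1, 2571 of the 5303 were called again in all 5. For the other 8 pairs of factors, 6693 to 7326 genes were called in the same direction, with r from 0.701 to 0.855 and a covariance above the simulated one by 0.496 to 0.607. LDHA, the lactate dehydrogenase of glycolysis, fell from 748 ± 5.8 CPM in Control to 169 ± 28 in OSR1, 188 ± 0.65 in OSR2, 173 ± 1.3 in EGR1, 157 ± 10 in KLF2 and 198 ± 5 CPM in KLF4 (adjusted p between 4.2e-07 and 2.6e-06). The endoplasmic reticulum stress list was not called between a factor and those of the other families (adjusted p = 0.38, 0.26, 0.11, 0.63 and 0.89). The hypoxia and glycolysis list was lower there in OSR1 (7 of 29 lower, 2 higher, adjusted p = 0.014, 0.31 with an estimated correlation). It was not called for the other 4 factors (adjusted p = 0.096, 0.14, 0.24 and 0.14). Among the 6 genes with the largest mean change in all 5 comparisons, COI and ADH4 had no counts in the 10 factor libraries and 4.59 ± 4.5 and 1.57 ± 1.4 CPM in Control. NME4 and RAX had none in Control. NRSN2 lay at 0.00825 ± 0.012 and NOS3 at 0.0506 ± 0.045 CPM in Control, against 0.311 ± 0.25 and 0.789 ± 0.81 CPM in OSR1, so no fold change is given for these genes. The NOS3 call in OSR1 ended without Control replicate 1 (adjusted p = 0.104) and without Control replicate 2 (0.0534, range 7.2e-05 to 0.1).

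**Figure D3:**
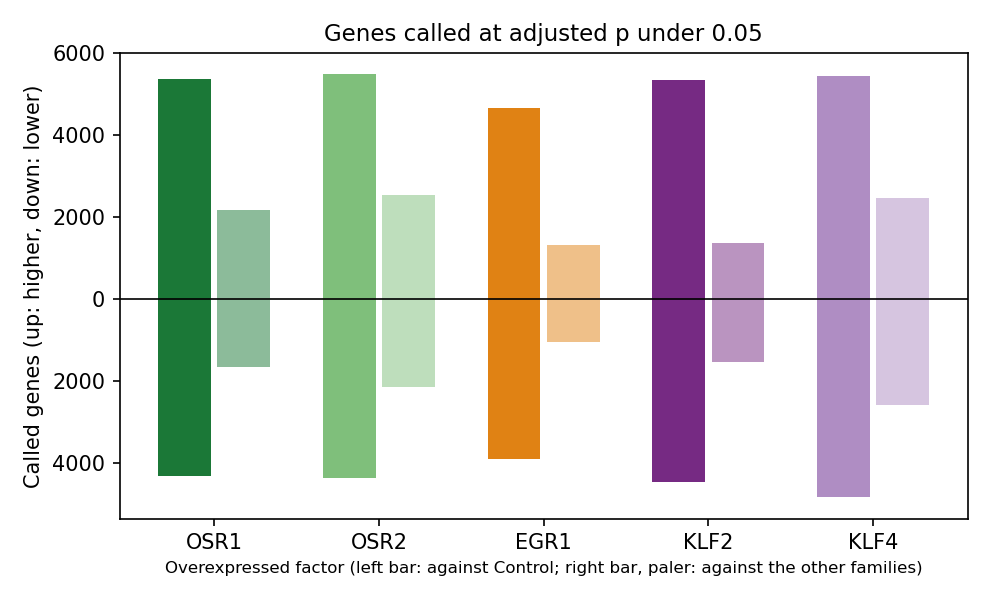
Genes called at an adjusted p under 0.05, higher (up) and lower (down), for each factor against Control (left bars) and against the factors of the other families (paler right bars). Calls against Control range from 8559 in EGR1 to 10284 in KLF4.

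**Figure D4:**
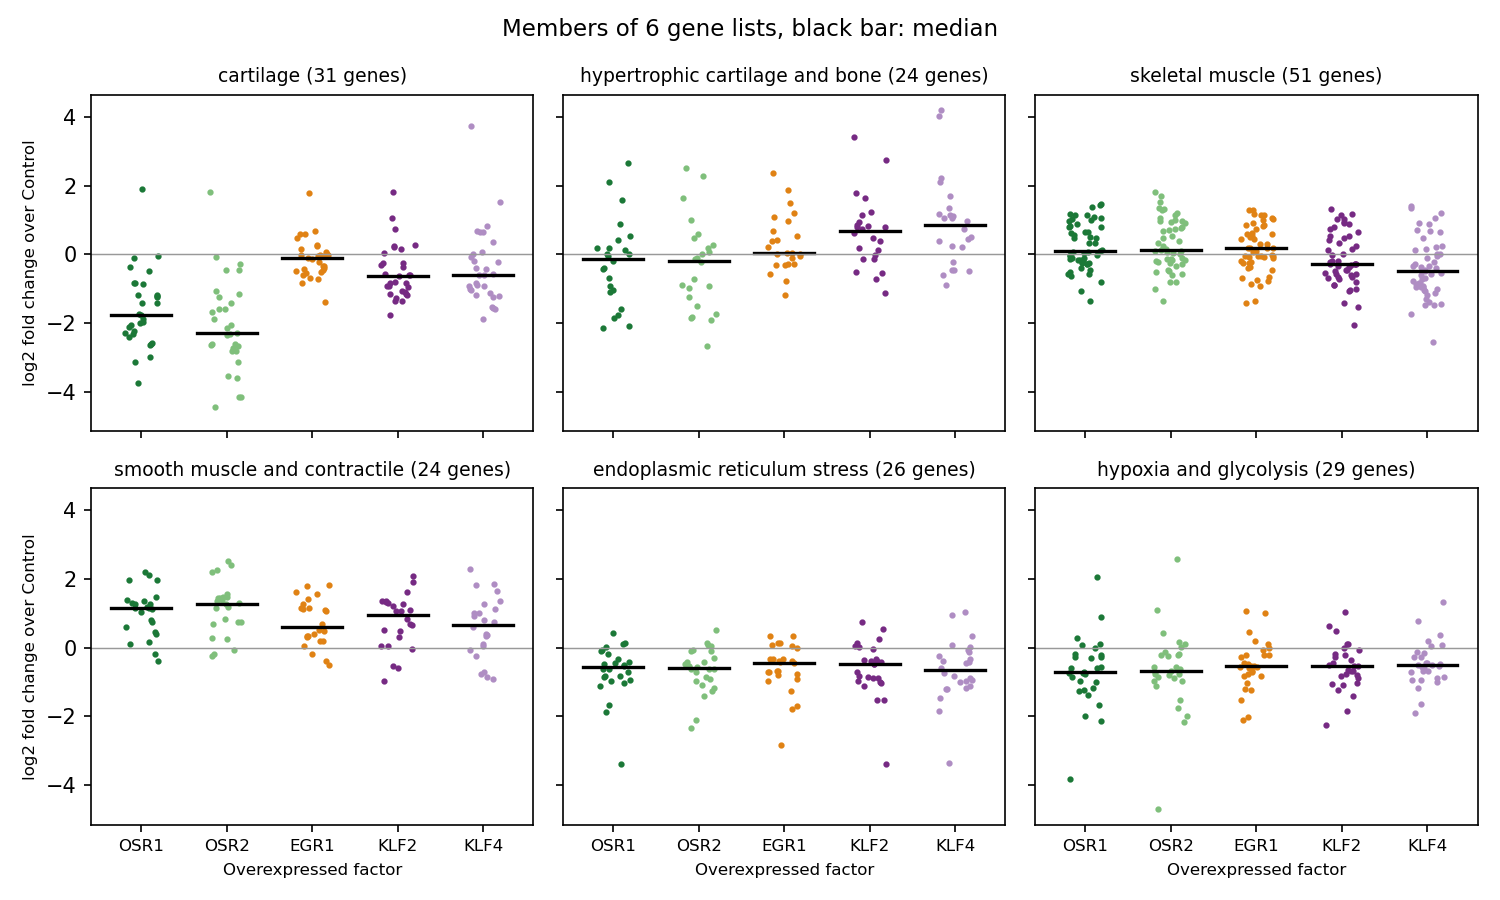
Log2 fold change over Control of each measured member of 6 gene lists, 1 point per gene in each of the 5 factors, with a black bar at the median. The median of the cartilage list is -1.76 in OSR1, -2.29 in OSR2, -0.12 in EGR1, -0.64 in KLF2 and -0.61 in KLF4.

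Of 28 lists, 8 were called in all 5 comparisons with Control, and their values follow in the order OSR1, OSR2, EGR1, KLF2 and KLF4. Fibrillar and loose connective tissue genes rose in each comparison, with 24, 26, 21, 23 and 21 of 35 measured members higher and at most 5 lower (25, 26, 21, 23 and 21 higher and at most 5 lower adjusted over the list alone). COL1A1 (1.49, 1.5, 1.56, 1.67 and 2.09) was among them (camera adjusted p = 7.1e-10 to 0.00044, 0.19 to 0.36 with an estimated correlation). Smooth muscle and contractile genes rose in each comparison, with 19, 20, 16, 18 and 14 of 24 measured members higher and at most 4 lower (19, 20, 18, 18 and 15 higher and at most 4 lower adjusted over the list alone). TAGLN (2.19, 2.41, 1.81, 1.90 and 1.83) and CNN1 (1.96, 2.25, 1.42, 1.36 and 1.14) were among them (camera adjusted p = 9.3e-12 to 0.0037, adjusted p = 0.2 to 0.45 with an estimated correlation). The TGF-beta signalling list rose in each comparison, with 17, 16, 11, 15 and 18 of 23 measured members higher and at most 1 lower (18, 17, 13, 15 and 18 higher and at most 1 lower adjusted over the list alone). TGFB3 (0.64, 0.59, 0.72, 1.05 and 0.80) and LTBP2 (2.18, 2.37, 1.12, 1.39 and 1.88) were among them (camera adjusted p = 5.7e-06 to 0.0018, adjusted p = 0.33 to 0.39 with an estimated correlation). Retinoic acid pathway genes rose in each comparison, with 9, 11, 9, 10 and 12 of 17 measured members higher and at most 3 lower (9, 11, 10, 10 and 12 higher and at most 3 lower adjusted over the list alone). CRABP2 (1.51, 1.87, 0.60, 1.97 and 2.27) and RARA (1.12, 1.37, 1.39, 1.45 and 1.48) were among them (camera adjusted p = 2.5e-06 to 0.029, adjusted p = 0.054 to 0.33 with an estimated correlation). Without Control replicate 1 the retinoic acid list in EGR1 was at adjusted p = 0.053 (0.001 to 0.33). Axon guidance and chemokine genes rose in each comparison (camera adjusted p = 2.2e-06 to 0.00026, adjusted p = 0.36 to 0.41 with an estimated correlation), which had 29, 31, 25, 32 and 28 of 47 measured members higher and at most 6 lower (32, 33, 25, 34 and 29 higher and at most 6 lower adjusted over the list alone). Immediate early genes rose in each comparison, with 15, 16, 13, 14 and 15 of 21 measured members higher and at most 3 lower (16, 16, 13, 14 and 15 higher and at most 4 lower adjusted over the list alone). Camera gave this list adjusted p = 0.00013 to 0.02 (0.36 to 0.5 with an estimated correlation). Endoplasmic reticulum stress genes fell in each comparison, with 18, 18, 19, 19 and 16 of 26 measured members lower and at most 3 higher (19, 19, 19, 19 and 18 lower and at most 3 higher adjusted over the list alone). HSPA5 (-0.95, -1.07, -0.80, -0.88 and -1.10) and ASNS (-1.87, -2.10, -1.69, -1.53 and -1.83) were among them (camera adjusted p = 2.4e-08 to 4.5e-07, adjusted p = 0.2 to 0.22 with an estimated correlation). Against the factors of the other families, smooth muscle genes were higher in OSR1 (adjusted p = 9.4e-06, 0.57 with an estimated correlation) and OSR2 and lower in EGR1, KLF2 and KLF4 (4, 6 and 12 of 24 lower, adjusted p = 0.04, 0.0075 and 0.00019, with an estimated correlation 0.77, 0.77 and 0.65), so their direction turned with the reference in 3 factors. There retinoic acid genes were lower in EGR1 (adjusted p = 0.00015, 0.11 with an estimated correlation) and higher in KLF4 (adjusted p = 0.0051, 0.28 with an estimated correlation). In these contrasts immediate early genes were not called (adjusted p = 0.17, 0.091, 0.097, 0.082 and 0.95). TGF-beta genes (adjusted p = 0.0014, 0.65 with an estimated correlation) and axon guidance genes (0.0027 and 0.75) were called only as lower in EGR1. The other 4 factors were at adjusted p from 0.24 to 0.81 and from 0.34 to 0.51. Hypoxia and glycolysis genes fell in each comparison, with 19, 18, 19, 20 and 20 of 29 measured members lower and at most 3 higher (21, 19, 20, 21 and 21 lower and at most 4 higher adjusted over the list alone). LDHA (-2.14, -1.99, -2.11, -2.25 and -1.91) and NDRG1 (-1.99, -2.16, -1.22, -1.24 and -1.18) were among them (camera adjusted p = 3.7e-13 to 4.5e-07, adjusted p = 0.035 to 0.054 with an estimated correlation). Ribosomal protein genes rose as a list in OSR1, OSR2, EGR1 and KLF2 (camera adjusted p = 0.0015, 0.00047, 0.0025 and 0.0061, adjusted p = 0.57, 0.55, 0.59 and 0.61 with an estimated correlation), and camera adjusted p was 0.24 in KLF4. Over the 5 factors, 40, 42, 30, 33 and 24 of 73 ribosomal genes were higher and 1, 2, 3, 2 and 6 lower (40, 42, 30, 33 and 23 and 1, 2, 3, 1 and 5 adjusted over the list alone). RPL19 rose (0.58, SE 0.10 in OSR1), as did RPS13 (0.82, SE 0.11) in OSR2, and RPL22L1 fell (-0.90, SE 0.13 in KLF4). The ribosomal list was at adjusted p = 0.14 without OSR1 replicate 1 (1.1e-07 to 0.57) in OSR1, 0.05 without Control replicate 1 (5.2e-05 to 0.61) in KLF2 and 0.017 without Control replicate 2 (0.017 to 0.85) in KLF4.

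Several lists were not called in any of the 5 comparisons with Control. The tendon list had 8 to 11 of 23 members higher and 6 to 8 lower (10 to 11 and 7 to 8 adjusted over the list alone, camera adjusted p = 0.3 to 0.93). Its transcription factor SCX rose with each factor (2.43, 2.21, 2.02, 2.0 and 2.17 in the order OSR1, OSR2, EGR1, KLF2, KLF4, SE 0.50). In OSR1 it was at 3.07 without OSR1 replicate 1 and 1.28 without OSR1 replicate 2 (adjusted p = 0.06 in a fit of the 4 libraries alone, 3.3e-08 to 0.06). Without Control replicate 1 SCX was not called in the other 4 (adjusted p = 0.0598, 0.0896, 0.0789 and 0.0577, with ranges up to 0.06, 0.09, 0.079 and 0.058). Matrix remodelling had 15 to 18 of 33 members higher and 7 to 11 lower (16 to 18 and 9 to 11 adjusted over the list alone, camera adjusted p = 0.057 to 0.21). It was called in OSR1 at adjusted p = 0.03 without OSR1 replicate 1 (0.03 to 0.65), in KLF2 at 0.032 without KLF2 replicate 2 (0.032 to 0.59) and in EGR1 at 0.046 without EGR1 replicate 1 and 0.032 without EGR1 replicate 2 (0.023 to 0.52). Blood and leukocyte genes had 8 to 11 of 23 members higher and 1 to 4 lower (8 to 12 and 1 to 4 adjusted over the list alone, camera adjusted p = 0.096 to 0.59), with the macrophage complement gene C1QA at 1.27, SE 0.28 in OSR1 and 1.52, SE 0.28 in OSR2. The list was called in KLF4 at adjusted p = 0.042 without KLF4 replicate 2 (0.0012 to 0.44). Neural crest, glial, neuronal and pigment genes had 6 to 11 of 25 members higher and 4 to 6 lower (6 to 12 and 4 to 7 adjusted over the list alone, camera adjusted p = 0.12 to 0.91). The neurofilament gene NEFM rose by 1.71, SE 0.15 in OSR1 and 2.31, SE 0.15 in OSR2. The p53 and cell death list had 10 to 12 of 26 members higher and 3 to 5 lower (10 to 12 and 2 to 5 adjusted over the list alone, camera adjusted p = 0.077 to 0.19), and its cell cycle inhibitor CDKN1A rose by 0.83, 0.81, 0.93, 1.22 and 1.34 in the order OSR1, OSR2, EGR1, KLF2, KLF4. Interferon response genes had 13 to 17 of 43 members higher and 6 to 14 lower (14 to 17 and 6 to 14 adjusted over the list alone, camera adjusted p = 0.31 to 0.91). BMP and GDF signalling genes had 11 to 18 of 31 members higher and 5 to 8 lower (11 to 18 and 5 to 8 adjusted over the list alone, camera adjusted p = 0.05 to 0.24).

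Other lists were called for some factors and not for the rest. Endothelial genes had 6 to 13 of 28 higher and 4 to 5 lower (5 to 14 and 4 to 5 adjusted over the list alone, camera adjusted p = 0.2 to 0.68) in OSR1, OSR2, EGR1 and KLF2. Epithelial genes had 4 to 8 of 42 higher and 0 to 2 lower (3 to 7 and 0 to 2 adjusted over the list alone, camera adjusted p = 0.24 to 0.74) in these 4. The list was called in EGR1 at adjusted p = 0.019 without EGR1 replicate 1 (0.019 to 0.97). The adipocyte and lipid storage list had 9 to 12 of 21 higher and 2 to 4 lower (10 to 12 and 2 to 4 adjusted over the list alone, camera adjusted p = 0.11 to 0.23) in the same 4. Hypertrophic cartilage and bone genes had 7 of 24 measured members higher, 5 lower and 12 not called (7 and 5 adjusted over the list alone, camera adjusted p = 0.41) in EGR1. WNT signalling genes in EGR1 had 16 of 44 measured members higher, 8 lower and 20 not called (16 and 8 adjusted over the list alone, camera adjusted p = 0.2). FGF and MAPK feedback genes had 11 to 14 of 26 higher and 4 to 8 lower (11 to 14 and 4 to 8 adjusted over the list alone, camera adjusted p = 0.089 to 0.19) in OSR2, EGR1, KLF2 and KLF4. Notch signalling in OSR2 had 11 of 22 measured members higher, 3 lower and 8 not called (11 and 3 adjusted over the list alone, camera adjusted p = 0.15). The Hedgehog list had 7 of 14 higher and 2 to 5 lower (7 to 8 and 2 to 5 adjusted over the list alone, camera adjusted p = 0.095 to 0.83) in OSR2 and KLF4. The cell cycle list had 11 to 19 of 44 higher and 2 to 15 lower (12 to 19 and 2 to 16 adjusted over the list alone, camera adjusted p = 0.11 to 0.99) in OSR1, OSR2 and KLF4. The median, mean and test of a list differed in sign in 6 lists without a call, which were tendon and neural genes in KLF2, cell cycle genes in OSR1 and OSR2, Hedgehog genes in OSR2 and interferon genes in EGR1. Of 69 list calls in the 5 comparisons with Control, 5 held with an estimated correlation, those of cartilage in OSR2 and of hypoxia and glycolysis in OSR1, OSR2, EGR1 and KLF2.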

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

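The contrasts with the other families, and the tests of how many genes called with all 5 factors are called again, were added after the data were seen, of which those by thinning and scaling were set before their own results were seen. Of 505 named gene results, median-of-ratios scaling left 505 with the same direction and side of the threshold, library totals 496, no filter 494 and the 1.5-fold test 381. DESeq2 left 481 of the 504 it gave a value for, thinning to the smallest total 496 of 500, and a fit of the 2 groups 474 of 493. No named gene or list changed direction past the threshold in these fits or with 1 library left out, though some did against the other families. With 1 library left out, 1784 gene results stayed, 224 lost their call and 12 gained one, and of the list results 525 stayed, 17 lost and 18 gained a call. Leaving out a library leaves an arm with 1 library, which is assumed to vary like the other groups. Of the 140 list results, 64 lost their call with an estimated correlation, and fry added 49 calls and removed 1. Library totals moved the median of all genes most in EGR1, by -0.0857 on the log2 scale, and the share of called genes that were higher went from 54.6% to 45.2% in EGR1, from 54.5% to 49.8% in KLF2 and from 53% to 49.1% in KLF4.

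A demand for 1.5-fold change left 2 called genes between OSR1 and OSR2 but moved the other counts, to 2417 in OSR1, 2972 in OSR2, 1280 in EGR1, 2820 in KLF2, 3850 in KLF4, 72 between KLF2 and KLF4, 2195 shared by OSR1 and OSR2 and 2395 shared by KLF2 and KLF4, which its own construction explains. Against the other families the counts were 3813, 4686, 2374, 2888 and 5041 in the order OSR1, OSR2, EGR1, KLF2, KLF4. DESeq2 called 35 genes between OSR1 and OSR2 and 773 between KLF2 and KLF4, and a fit of the 2 groups called 258 between KLF2 and KLF4. With 1 library left out, counts ran from 5807 to 8833 in OSR1, 6362 to 8500 in OSR2, 4597 to 7439 in EGR1, 6303 to 9241 in KLF2 and 7205 to 8470 in KLF4. They ran from 2 to 103 between OSR1 and OSR2, from 93 to 471 between KLF2 and KLF4, from 5308 to 8005 for calls shared by OSR1 and OSR2, and from 5262 to 8202 for those shared by KLF2 and KLF4. Of the 5303 genes called with all 5 factors, 687 passed the 1.5-fold test, 2571 were called again without Control replicate 1 and 4016 without Control replicate 2. Apart from the 1.5-fold test, the cause was not tested. Simulations against Control made only 115 to 138 calls, so their 50% to 75.8% recovery of 2-fold changes need not hold here.

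The replicate numbers did not pair libraries. Across 15 pairs of groups, the replicate differences correlated across genes with r from -0.29 to 0.222, and 4 of 12 libraries were closest to a library of their own number. With the number as a block, 5 genes were called between OSR1 and OSR2 (the cause was not tested), 500 named gene results stayed, 3 lost and 2 gained a call, and 137 list results stayed, 1 lost and 2 gained a call.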

Other observations

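The test of variation within groups, the test of a uniform change of vector RNA and the contrasts with the other families were chosen only after the results were seen.

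Some genes of matrix turnover and cell regulation, chosen after their values were seen, moved with the OSR or the KLF factors. The serine protease HTRA3 rose by 2.28, SE 0.11 in OSR1 and 2.54, SE 0.11 in OSR2 libraries, the transcription cofactor LMO2 by 2.06, SE 0.17 and 2.29, SE 0.17, and the protease inhibitor TIMP4 fell (-1.58, SE 0.08 and -1.82, SE 0.08). The cross-linking enzyme LOXL4 rose by 3.24, SE 0.31 in KLF2 and 4.13, SE 0.31 in KLF4, and the inhibitor TIMP3 by 1.97, SE 0.32 and 3.01, SE 0.32. PERP, a gene of desmosomes, fell in OSR1 (-1.65, SE 0.21) and OSR2 (-1.91, SE 0.21), rose in KLF4 (1.91, SE 0.20) and was lower in KLF2 than in KLF4 (-1.65, SE 0.20, adjusted p = 0.0031). SMAD6, an inhibitor of BMP signalling, rose with each factor (1.17, 1.30, 0.91, 1.17 and 1.05 in the order OSR1, OSR2, EGR1, KLF2, KLF4). EGR1 counts rose in OSR2 libraries (0.50, SE 0.15, adjusted p = 0.016), but not past the threshold without Control replicate 1 (adjusted p = 0.109), OSR2 replicate 1 (0.0719) or OSR2 replicate 2 (0.0514), with a range of 0.0015 to 0.93 over the alternatives.

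The 5303 genes called alike against Control with all 5 factors are the first pattern. Lower depth of the Control libraries is argued against by thinning, after which 92.3% of these genes were called again, and the choice of scaling by the 92.5% called again under the scaling that kept fewer. A source of variation that also separates replicates of a group may contribute, since the difference between a group's replicates correlated across these genes with the mean change of the other 4 factors (r = 0.521 in OSR1, 0.548 in OSR2, -0.55 in EGR1, -0.533 in KLF2 and 0.175 in KLF4, with 0.55 the largest in size), although over all 18979 genes, the set first used, the largest r was 0.345. A batch that holds both Control libraries, which the labels do not give, cannot be told apart from an effect of carrying an insert, because no factor library would share it. A response of the cells common to the 5 factors stays open as untested.

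The entries gag, pol, env and ERVK-11 are lower with each insert than with the empty vector. The 7 other entries with endogenous retroviral names argue against a shift of this size in all such loci. Their median log2 fold change was -0.29 in KLF2 and -0.27 in KLF4, against -2.02 and -1.71 for gag, pol, env and ERVK-11. A smaller or partial shift stays open, as ERVK-11 bears such a name and ERVK-9 fell too. The fall differed between env and gag by up to 5.52 standard errors (KLF4, env minus gag -0.855, SE 0.155). Unequal endogenous reads would give this too, so 1 change in vector RNA cannot be told apart from a changed balance of its transcripts. Why inserts lower these counts was not tested.

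OSR1 and OSR2 differ in 2 called genes. The 95% interval of their difference lay within 2-fold for 91.1% of the genes called alike against Control, but these genes were chosen for likeness. Simulations recovered 28.7% of 1.5-fold, 64.9% of 2-fold and 90.1% of 4-fold changes, but made 254 calls against 2, so recovery here can be lower. Likeness cannot be told apart from low precision. More genes were called when either OSR1 replicate was left out. With 1 OSR1 library left, such calls can be traits of that library. They cannot show whether spread of 1 library hides further differences. The smaller fall of cartilage genes in OSR1 is therefore a hypothesis. Whether it follows from the factor or the expression level of each vector was not tested.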
